A study of Mus musculus with 50 samples.

How the data were processed

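RNA was extracted from lymph nodes with TRIzol and libraries were made with a poly(A) selection kit, per the labels' protocols. The 50 libraries fall into 10 groups of 5, 1 for each of 2 diets and 5 nodes, and no library was left out. The values used were estimated counts per gene, which the authors deposited in 1 table with 56600 gene entries, of which 379 had no gene name. The submitters' processing notes name kallisto, limma and edgeR and the builds GRCm39 and mm10, and their roles and versions are not given in the sources used here. Of the nonzero deposited estimated counts, 0.122% were whole numbers to within 1e-06. The columns of the deficient libraries carry the word 3rd, whose meaning is not given in the sources used here, and they were assigned to the deficient diet because the other 25 columns are named control. Dams were fed 1 diet or the other from before mating, so no litter holds both diets. Litter and dam therefore cannot be told apart from the diet, and the number of litters per diet was not available here.

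Estimated counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr, which left 18387 genes, and libraries were scaled with TMM. One model with a mean for each diet and node and a term for sex was fitted to all 50 libraries with edgeR's quasi-likelihood functions (edgeR 4.0.16, limma 3.58.1, R 4.3.3). Because all deficient mice were female, the sex term rests on the sufficient libraries alone. Within each diet, gut-draining nodes were compared with inguinal nodes, small intestinal with colonic nodes, and duodenal with ileal nodes, where each side is the mean of its nodes. The deficient diet was compared with the sufficient diet in each node, and interaction terms compared the diet effect between regions. P-values were adjusted with the Benjamini-Hochberg method over all genes tested in a comparison, with a threshold of 0.05. Standard errors were derived from the log2 fold change and the F statistic and are approximate. Expression levels are TMM-normalised CPM.

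Fixed lists of marker genes (37 lists) were tested with limma's camera on voom values, with a preset correlation between genes of 0.01 and again with the correlation estimated from the data, adjusted over lists and comparisons. Members past the threshold were counted over all genes, and again with adjustment over the list alone. The lists, comparisons, tests and all alternatives not described as added were chosen before the data were examined. The rule for genes named in the text was set at the same time. It took up to 10 genes per direction with the largest changes and at least 5 CPM, up to 4 genes per list with the smallest adjusted p, and 12 set genes. Positions were looked up by Ensembl identifier in GENCODE M21, which holds 51486 of the 56600 identifiers.

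Alternatives were RLE size factors, no filter, a filter on CPM of at least 1 in at least 5 libraries, limma-voom, DESeq2 1.42.0, no sex term, female mice only, the libraries of 1 node or 1 diet only, the replicate number as a block, and leaving out each number of a diet in turn. Leaving out 10 libraries with a low share of Gm19220, a term for that class, and leaving out 2 libraries with a high pancreatic share were added after the data were seen. A comparison of the diets on means per mouse had been planned and is not reported, because the sources used here do not tie the nodes to individual mice. The fits were tested on simulated counts with 100 genes changed by a log2 fold change of 1. For the deficient against sufficient diet in duodenal nodes 54 of them were recovered among 18078 genes, and 17 of 100 changed by 0.5. Of all calls there 6.58% were unchanged genes, somewhat above the threshold. That share was 8.08% for duodenal against ileal nodes on the sufficient diet and 2.88% for gut-draining against inguinal nodes. The simulated libraries were independent of one another, without a sex effect or a correlation between nodes of a number. These shares hold for that setting only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.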

Results

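The data set held 50 poly(A) RNA sequencing libraries of mouse lymph nodes taken at postnatal day 56. The mice were offspring of dams that were fed a diet with vitamin A at 20 IU/g (sufficient) or a diet lacking vitamin A (deficient), starting 3 weeks ahead of mating. Vitamin A is the precursor of retinoic acid, which is made from retinal by aldehyde dehydrogenases and acts through nuclear receptors. Nodes draining the duodenum, jejunum, ileum and colon were collected together with the inguinal node, which drains skin. Each of the 10 combinations of diet and node held 5 libraries. Every deficient library came from a female mouse, whereas sufficient libraries 1 and 2 of each node came from females and libraries 3, 4 and 5 from males. Xist, the transcript of the inactive X chromosome, lay between 495 and 875 normalised CPM in the 35 female libraries and between 1.53 and 57.1 CPM in the 15 male libraries. Estimated counts per library totalled 5335370 to 8904720, with a median of 7640370, and 22943 to 25705 genes had a count. In what follows, values in parentheses after a gene are the log2 fold change ± its standard error and the Benjamini-Hochberg adjusted p of edgeR's quasi-likelihood test over 18387 genes, with 5 libraries for each diet and node. Levels in CPM are means ± SD with n = 5. The labels do not say which nodes came from the same mouse, so p-values measure the spread between libraries.

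Gut-draining nodes were first compared with inguinal nodes on the sufficient diet, to see what sets nodes of the intestine apart from a skin-draining node. The homeobox factor Nkx2-3, which acts in the endothelium of gut-associated lymphoid organs, averaged 7.57 ± 1.45, 11.4 ± 1.4, 9.5 ± 2.46 and 11.6 ± 3.92 CPM in duodenal, jejunal, ileal and colonic nodes and 0.0302 ± 0.068 CPM in inguinal nodes (adjusted p = 1.4e-18). Its target Madcam1, the mucosal vascular addressin, rose with it (log2 fold change 2.97 ± 0.21, adjusted p = 1.2e-14). The retinoic acid-producing enzyme Aldh1a2 was higher in gut-draining nodes (log2 fold change 3.82 ± 0.29, adjusted p = 1.4e-13), as was Lrat, which esterifies retinol for storage (log2 fold change 3.23 ± 0.26, adjusted p = 5.5e-13). The IgA heavy chain gene Igha averaged 2313 ± 381 CPM in duodenal and 19 ± 13.5 CPM in inguinal nodes (log2 fold change 7.00 ± 0.52, adjusted p = 6.9e-14). In all, 3108 genes passed, 1781 of them higher and 1327 lower in gut-draining nodes.

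The retinoid metabolism list (camera adjusted p = 4.6e-05, adjusted p = 0.0108 with an estimated correlation) and the retinoic acid response list (camera adjusted p = 9.7e-05, adjusted p = 0.0362 with an estimated correlation) were both higher in gut-draining nodes. Among 18 tested retinoid metabolism genes, 9 were higher and 1 lower over all genes, and 9 and 2 adjusted over the list alone. Of 15 tested retinoic acid response genes, 9 were higher and 2 lower over all genes, and 9 and 3 adjusted over the list alone. Their members included the retinaldehyde reductase Dhrs3 (1.33 ± 0.14, adjusted p = 1.2e-09), the retinol importer Stra6 (1.84 ± 0.26, adjusted p = 9.8e-07) and the transcriptional repressor Hic1 (1.32 ± 0.13, adjusted p = 2.2e-10). The retinoic acid hydroxylase Cyp26b1, which degrades retinoic acid, went the other way and was lower in gut-draining nodes (log2 fold change -1.54 ± 0.23, adjusted p = 1.6e-06). Lymphatic endothelial genes were higher (camera adjusted p = 5.1e-20, adjusted p = 0.00258 with an estimated correlation), among them the hyaluronan receptor Lyve1 (1.42 ± 0.13, adjusted p = 7.7e-12), the scavenger receptors Marco (2.10 ± 0.17, adjusted p = 3.8e-13) and Stab2 (1.25 ± 0.13, adjusted p = 1.0e-09) and the lectin Clec4g (2.63 ± 0.24, adjusted p = 3.2e-11). Among 16 tested lymphatic endothelial genes, 15 were higher and 0 lower over all genes, and 16 and 0 adjusted over the list alone. Fibroblast genes of the adventitia and capsule were higher under the preset correlation (camera adjusted p = 3.5e-07, adjusted p = 0.101 with an estimated correlation), including the matrix genes Lum (3.27 ± 0.19, adjusted p = 1.5e-17) and Col14a1 (1.94 ± 0.16, adjusted p = 1.7e-12). Of 15 tested fibroblast genes, 9 were higher and 2 lower over all genes, and 11 and 2 adjusted over the list alone. Macrophage genes of sinus and medulla (camera adjusted p = 1.4e-05, adjusted p = 0.227 with an estimated correlation) were split, since Adgre1 (1.49 ± 0.16, adjusted p = 2.5e-09), which encodes F4/80, rose on average while the phosphatidylserine receptor Timd4 (-1.40 ± 0.10, adjusted p = 3.6e-15) fell. Among 17 tested macrophage genes, 11 were higher and 3 lower over all genes, and 11 and 3 adjusted over the list alone. The rise of Adgre1 came from small intestinal nodes, since it averaged 17 ± 4.07 CPM in colonic and 16.8 ± 3.32 CPM in inguinal nodes.

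Genes of T cells (camera adjusted p = 2.7e-11, adjusted p = 0.0482 with an estimated correlation) and of B cells (camera adjusted p = 1.9e-08, adjusted p = 0.0649 with an estimated correlation) were lower in gut-draining than in inguinal nodes, with small changes in the interleukin 7 receptor Il7r (-0.71 ± 0.10, adjusted p = 1.1e-06), in Cd3g (-0.48 ± 0.08, adjusted p = 2.0e-05), in Ms4a1 (-0.35 ± 0.07, adjusted p = 3.5e-04) and in Bank1 (-0.43 ± 0.07, adjusted p = 5.2e-06). Of 16 tested T cell genes, 0 were higher and 13 lower over all genes, and 0 and 16 adjusted over the list alone. Among 15 tested B cell genes, 0 were higher and 13 lower over all genes, and 0 and 13 adjusted over the list alone. Interferon response genes were lower (camera adjusted p = 4.3e-06, adjusted p = 0.472 with an estimated correlation), for example Oas3 (-1.58 ± 0.33, adjusted p = 5.3e-04). Of 18 tested interferon response genes, 0 were higher and 13 lower over all genes, and 0 and 15 adjusted over the list alone. The inguinal node was marked by the trunk patterning factor Tbx15 (-5.26 ± 0.43, adjusted p = 6.1e-13), the chemokine Ccl8 (-4.50 ± 0.24, adjusted p = 1.4e-18) and the follicular chemokine Cxcl13 (-1.16 ± 0.10, adjusted p = 7.9e-12). The langerin gene Cd207 (-2.20 ± 0.25, adjusted p = 5.2e-09), found in Langerhans cells and related dendritic cells, was also higher there. Genes of other tissues moved with this contrast. Of 21 pancreatic genes, 20 were higher in gut-draining nodes (camera adjusted p = 0.0854), and adipose genes moved in the same direction (camera adjusted p = 3.4e-05, adjusted p = 0.481 with an estimated correlation). Among 17 tested adipose genes, 6 were higher and 2 lower over all genes, and 13 and 2 adjusted over the list alone. Among female mice alone 1136 genes passed in this contrast.

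On the deficient diet the contrast of gut-draining against inguinal nodes called 1050 genes, 683 higher and 367 lower. Nkx2-3 had no count in any of the 5 deficient inguinal libraries and averaged 7.75 ± 1.6 CPM in deficient ileal nodes (adjusted p = 2.1e-18). Igha and Madcam1 were again higher in gut-draining nodes (log2 fold change 5.96 ± 0.49, adjusted p = 2.0e-12, and 2.27 ± 0.20, adjusted p = 1.8e-11), and so was Lum (3.49 ± 0.19, adjusted p = 5.1e-18). Aldh1a2 did not pass (log2 fold change 0.82 ± 0.32, adjusted p = 0.146), and Lrat was lower in gut-draining nodes (log2 fold change -0.90 ± 0.24, adjusted p = 0.0114). Cyp26b1 was far lower in gut-draining than in inguinal nodes (-4.19 ± 0.25, adjusted p = 6.6e-17), with 12 ± 1.91 CPM in deficient inguinal nodes. Neither retinoid list passed here (camera adjusted p = 0.713 and 0.215). Plasma cell genes were higher (camera adjusted p = 3.9e-18, adjusted p = 0.00377 with an estimated correlation), including the joining chain Jchain (2.77 ± 0.40, adjusted p = 2.1e-06) and the secretory factor Xbp1 (0.67 ± 0.11, adjusted p = 2.6e-05), as were lymphatic endothelial genes (camera adjusted p = 1.3e-18, adjusted p = 0.00338 with an estimated correlation). Of 19 tested plasma cell genes, 12 were higher and 0 lower over all genes, and 14 and 1 adjusted over the list alone. Among 16 tested lymphatic endothelial genes, 9 were higher and 0 lower over all genes, and 11 and 0 adjusted over the list alone. Genes of neutrophils and monocytes were lower (camera adjusted p = 1.9e-08, adjusted p = 0.0368 with an estimated correlation), such as the calprotectin subunit S100a9 (-2.53 ± 0.55, adjusted p = 0.0017). Of 15 tested neutrophil and monocyte genes, 0 were higher and 6 lower over all genes, and 0 and 9 adjusted over the list alone. High endothelial venule genes were lower too (camera adjusted p = 1.5e-06, adjusted p = 0.00776 with an estimated correlation), among them the sulfotransferase Chst4 (-1.02 ± 0.16, adjusted p = 1.4e-05) and the L-selectin ligand Glycam1 (-0.98 ± 0.17, adjusted p = 9.8e-05). Among 15 tested high endothelial venule genes, 1 were higher and 6 lower over all genes, and 1 and 8 adjusted over the list alone. Ucp1 of brown fat averaged 8.56 ± 9.93 CPM in inguinal nodes (adjusted p = 1.0e-10). A group of 10 deficient libraries held a low share of counts in the processed pseudogene Gm19220 (1.03% to 1.7%, against 5.37% to 9.83% in the other 40), and without them 447 genes passed.

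Small intestinal nodes (duodenal, jejunal and ileal) were compared with colonic nodes to find the identity of small intestinal nodes. On the sufficient diet the macrophage gene Adgre1 (1.99 ± 0.17, adjusted p = 2.2e-11), the mannose receptor Mrc1 (1.21 ± 0.15, adjusted p = 2.0e-07), the guanylate-binding protein Gbp2b (2.72 ± 0.25, adjusted p = 1.7e-10) and the collagen Col6a6 (2.13 ± 0.22, adjusted p = 1.9e-09) were higher in small intestinal nodes. Aldh1a2 was higher too (log2 fold change 1.43 ± 0.23, adjusted p = 6.4e-05), with 49.4 ± 4.49 CPM in jejunal and 17.3 ± 2.65 CPM in colonic nodes, together with Lrat (1.03 ± 0.21, adjusted p = 0.00147) and Dhrs3 (0.63 ± 0.14, adjusted p = 0.00241). The posterior patterning genes Hoxc10 (-4.92 ± 0.37, adjusted p = 5.4e-12), Hoxa10 (-3.15 ± 0.44, adjusted p = 3.4e-06) and Hoxa9 (-2.26 ± 0.38, adjusted p = 1.0e-04) were higher in colonic nodes, as were Il22ra2 (-2.11 ± 0.17, adjusted p = 1.1e-11), the soluble inhibitor of interleukin 22, and the protease inhibitor Slpi (-2.41 ± 0.39, adjusted p = 5.3e-05). In total 705 genes passed, 487 higher and 218 lower in small intestinal nodes. Lymphatic endothelial genes (camera adjusted p = 1.1e-17, adjusted p = 0.00377 with an estimated correlation), the retinoid metabolism list (camera adjusted p = 6.8e-04, adjusted p = 0.0362 with an estimated correlation) and the retinoic acid response list (camera adjusted p = 2.5e-05, adjusted p = 0.0234 with an estimated correlation) were higher. Of 16 tested lymphatic endothelial genes, 9 were higher and 0 lower over all genes, and 12 and 0 adjusted over the list alone. Among 18 tested retinoid metabolism genes, 5 were higher and 0 lower over all genes, and 5 and 2 adjusted over the list alone. Of 15 tested retinoic acid response genes, 5 were higher and 0 lower over all genes, and 6 and 0 adjusted over the list alone. B cell genes were lower (camera adjusted p = 9.5e-11, adjusted p = 0.0362 with an estimated correlation), including Fcrla (-0.37 ± 0.07, adjusted p = 6.2e-04), and dendritic cell genes higher (camera adjusted p = 3.4e-05, adjusted p = 0.0362 with an estimated correlation), with the chemokine Ccl22 (0.75 ± 0.13, adjusted p = 8.3e-05) and the cross-presenting cell marker Clec9a (0.74 ± 0.14, adjusted p = 4.3e-04) up but the lectin Clec10a (-0.99 ± 0.14, adjusted p = 5.7e-06) down. Among 15 tested B cell genes, 0 were higher and 6 lower over all genes, and 0 and 13 adjusted over the list alone. Of 19 tested dendritic cell genes, 4 were higher and 1 lower over all genes, and 8 and 1 adjusted over the list alone. Pancreatic genes had a median log2 fold change of 3.53 in the same direction, with no member past the threshold over all genes, and adipose genes one of -0.78. Among female mice alone 79 genes passed, 48.1% of them higher against 69.1% in the full fit, and the count was 395 without sufficient replicate 3 and 465 without sufficient replicate 4.

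On the deficient diet genes of mast cells were higher in small intestinal nodes. The chymases Mcpt4 (3.71 ± 0.41, adjusted p = 4.4e-08) and Cma1 (3.63 ± 0.43, adjusted p = 2.0e-07), the carboxypeptidase Cpa3 (3.36 ± 0.38, adjusted p = 6.6e-08), the histamine-forming enzyme Hdc (2.15 ± 0.30, adjusted p = 6.5e-06) and, outside the mast cell list, the interleukin 33 receptor Il1rl1 (2.43 ± 0.31, adjusted p = 7.2e-07) all passed against colonic nodes. The list of mast cells, basophils and eosinophils was higher as a group (camera adjusted p = 2.4e-32, adjusted p = 2.1e-04 with an estimated correlation). Among 12 tested mast cell genes, 9 were higher and 0 lower over all genes, and 11 and 0 adjusted over the list alone. Igha was higher (1.79 ± 0.38, adjusted p = 0.00377), with 3048 ± 834 CPM in jejunal and 897 ± 527 CPM in colonic nodes. Dendritic cell genes were higher (camera adjusted p = 1.9e-08, adjusted p = 0.00433 with an estimated correlation), including the chemokines Ccl22 (1.46 ± 0.13, adjusted p = 2.9e-10) and Ccl17 (1.86 ± 0.29, adjusted p = 5.4e-05), and so were regulatory T cell genes (camera adjusted p = 1.6e-09, adjusted p = 0.00673 with an estimated correlation), for example Tnfrsf4 (0.65 ± 0.11, adjusted p = 8.9e-05), although its means were level in ileal (20.6 ± 2.2 CPM) and colonic nodes (20.4 ± 3.03 CPM). Of 19 tested dendritic cell genes, 8 were higher and 0 lower over all genes, and 10 and 2 adjusted over the list alone. Among 14 tested regulatory T cell genes, 2 were higher and 0 lower over all genes, and 7 and 0 adjusted over the list alone. The 2 were Tnfrsf4 and Il1rl1, which stands in the regulatory T cell list and is named above beside mast cell genes. Hoxc10 and Hoxa9 remained higher in colonic nodes (log2 fold change -4.94 ± 0.38, adjusted p = 1.5e-11, and -2.48 ± 0.37, adjusted p = 1.6e-05), with Il22ra2 (-1.49 ± 0.18, adjusted p = 2.0e-07) and the matrix protease Mmp3 (-1.90 ± 0.19, adjusted p = 4.4e-09). Aldh1a2 did not pass (0.14 ± 0.30, adjusted p = 0.948), and B cell genes were lower (camera adjusted p = 1.3e-10, adjusted p = 0.0362 with an estimated correlation). Of 15 tested B cell genes, 0 were higher and 4 lower over all genes, and 0 and 9 adjusted over the list alone. Pancreatic genes took 6.15% ± 10.7% of counts in deficient duodenal and 0.00409% ± 0.00263% in deficient colonic nodes. In deficient jejunal and ileal nodes they took 0.00663% ± 0.00603% and 0.00513% ± 0.00523%. In total 325 genes passed, 234 higher and 91 lower. Without the 10 libraries with low Gm19220 84 genes passed, 53.6% of them higher against 72% in the full fit. With a term for that class 234 genes passed, 68.4% of them higher. The count was 186, 172 and 193 without deficient replicates 1, 2 and 5 in turn.

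Along the small intestine, duodenal nodes were compared with ileal nodes. On the sufficient diet the endothelin receptor Ednrb (-2.61 ± 0.24, adjusted p = 8.3e-10), the macrophage gene Cd5l (-3.31 ± 0.34, adjusted p = 1.3e-08), the lymphatic growth factor receptor Flt4 (-1.50 ± 0.16, adjusted p = 1.3e-08) and the scavenger receptor Stab2 (-1.40 ± 0.15, adjusted p = 4.4e-08) were lower in duodenal nodes. Macrophage genes (camera adjusted p = 7.8e-15, adjusted p = 0.0173 with an estimated correlation), lymphatic endothelial genes (camera adjusted p = 3.6e-11, adjusted p = 0.0234 with an estimated correlation) and Hox genes (camera adjusted p = 2.8e-06, adjusted p = 0.0489 with an estimated correlation) were lower as groups, the last with Hoxd9 (-1.21 ± 0.18, adjusted p = 8.3e-06) and Hoxd10 (-1.60 ± 0.29, adjusted p = 2.2e-04). Among 17 tested macrophage genes, 0 were higher and 12 lower over all genes, and 0 and 12 adjusted over the list alone. Of 16 tested lymphatic endothelial genes, 1 were higher and 9 lower over all genes, and 2 and 12 adjusted over the list alone. Among 25 tested Hox genes, 0 were higher and 9 lower over all genes, and 0 and 11 adjusted over the list alone. Genes of germinal centre B cells were lower (camera adjusted p = 0.00342, adjusted p = 0.342 with an estimated correlation), including the transcription factor Mef2b (-2.77 ± 0.42, adjusted p = 1.4e-05). Of 16 tested germinal centre genes, 0 were higher and 5 lower over all genes, and 0 and 6 adjusted over the list alone. T cell genes were higher (camera adjusted p = 3.1e-11, adjusted p = 0.0484 with an estimated correlation), for example Cd8a (0.65 ± 0.11, adjusted p = 1.1e-04) and Trac (0.48 ± 0.10, adjusted p = 8.3e-04), and so were high endothelial venule genes (camera adjusted p = 1.5e-04, adjusted p = 0.0374 with an estimated correlation), such as Glycam1 (1.07 ± 0.24, adjusted p = 0.0020). Among 16 tested T cell genes, 10 were higher and 0 lower over all genes, and 13 and 0 adjusted over the list alone. Of 15 tested high endothelial venule genes, 7 were higher and 0 lower over all genes, and 7 and 0 adjusted over the list alone. All 21 pancreatic genes were higher in duodenal nodes (camera adjusted p = 9.3e-08, adjusted p = 0.462 with an estimated correlation), for example the lipase Pnlip (8.86 ± 1.98, adjusted p = 0.00217). Among 21 tested pancreatic genes, 21 were higher and 0 lower over all genes, and 21 and 0 adjusted over the list alone. Pancreatic genes took 0.0762% to 27.5% of counts in the 5 sufficient duodenal libraries. Adipose genes took 0.0606% ± 0.0245% of counts in sufficient duodenal and 0.148% ± 0.059% in sufficient ileal nodes. In total 1484 genes passed, 560 higher and 924 lower in duodenal nodes. Among female mice alone 136 genes passed, and the count was 958 without sufficient replicate 3 and 833 without sufficient replicate 4.

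On the deficient diet the endothelin receptor Ednrb (-3.24 ± 0.24, adjusted p = 4.5e-13), Cd5l (-3.53 ± 0.34, adjusted p = 1.0e-09) and the plasminogen activator Plat (-3.69 ± 0.43, adjusted p = 4.9e-08) were lower in duodenal than in ileal nodes, as were Flt4 (-1.32 ± 0.15, adjusted p = 6.2e-08) and Hoxd9 (-1.23 ± 0.18, adjusted p = 5.1e-06). Interferon response genes were lower (camera adjusted p = 4.5e-13, adjusted p = 0.208 with an estimated correlation), among them Rsad2 (-2.51 ± 0.58, adjusted p = 0.00395), Oas2 (-2.01 ± 0.39, adjusted p = 5.3e-04) and the regulator Irf7 (-1.92 ± 0.40, adjusted p = 0.00101). Of 18 tested interferon response genes, 0 were higher and 16 lower over all genes, and 0 and 18 adjusted over the list alone. The ileal libraries differed widely, with Rsad2 at 42.2 ± 46.8 CPM in ileal and 7.36 ± 1.22 CPM in duodenal nodes. Ileal replicate 4 held 125 CPM of Rsad2 and the other 4 held 10.6 to 28 CPM. Without deficient replicate 4 Rsad2 (-1.57, adjusted p = 0.153) and Irf7 (-1.35, adjusted p = 0.058) did not pass, while Oas2 did (-1.53, adjusted p = 0.0186). Regulatory T cell genes were higher (camera adjusted p = 1.0e-09, adjusted p = 0.00624 with an estimated correlation), including Tnfrsf4 (1.25 ± 0.12, adjusted p = 2.6e-09) and the inhibitory receptor Ctla4 (1.10 ± 0.18, adjusted p = 3.5e-05). Among 14 tested regulatory T cell genes, 8 were higher and 1 lower over all genes, and 10 and 1 adjusted over the list alone. The dendritic cell chemokines Ccl22 (2.11 ± 0.15, adjusted p = 2.2e-13) and Ccl17 (1.88 ± 0.30, adjusted p = 2.8e-05) and the migratory cell marker Fscn1 (1.40 ± 0.16, adjusted p = 2.9e-08) were higher in duodenal nodes. Macrophage genes were lower (camera adjusted p = 4.4e-12, adjusted p = 0.0362 with an estimated correlation), and all 21 pancreatic genes higher (camera adjusted p = 3.4e-06, adjusted p = 0.518 with an estimated correlation), with 0.00759% to 25.2% of counts in deficient duodenal libraries. Of 17 tested macrophage genes, 0 were higher and 6 lower over all genes, and 0 and 12 adjusted over the list alone. Among 21 tested pancreatic genes, 21 were higher and 0 lower over all genes, and 21 and 0 adjusted over the list alone. Adipose genes took 0.0742% ± 0.0615% of counts in deficient duodenal and 0.145% ± 0.0786% in deficient ileal nodes. In total 1029 genes passed, 533 higher and 496 lower. Without the 5 libraries of deficient replicate 4 474 genes passed, and without only the 2 libraries with a high pancreatic share 748.

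Regional differences were then compared between the diets, whose contrasts share no libraries. Across 18387 genes the log2 fold changes of the gut-draining against inguinal contrast had Pearson's r = 0.551, those of the small intestinal against colonic contrast r = 0.335 and those of the duodenal against ileal contrast r = 0.565. Genes are not independent replicates, so these values describe and do not test. Both contrasts also came from 1 fit with 1 estimate of spread per gene. A gene with a small spread thus passes more readily on both diets. The counts expected of independent lists ignore this, so the overlap below was not tested. Of the genes higher in gut-draining than in inguinal nodes, 515 passed on both diets, where 66.2 were expected of independent lists. Of those lower, 217 passed on both, where 26.5 were expected. For small intestinal against colonic nodes the shared calls were 112 higher (expected 6.2) and 40 lower (expected 1.08). For duodenal against ileal nodes they were 227 higher (expected 16.2) and 257 lower (expected 24.9). These shared counts depended on the libraries. Without the 10 libraries with low Gm19220 they were 273 higher and 107 lower, 17 higher and 17 lower, and 163 higher and 193 lower in the same order of contrasts. Among female mice they were 328 higher and 92 lower, 21 higher and 15 lower, and 29 higher and 60 lower. Expected counts fell too, for small intestinal against colonic nodes to 1.18 and 0.398 without the 10 libraries, where the excess of higher over lower calls was gone.

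The effect of the diet was tested in each node, deficient against sufficient. Technical measures also differed between the diets. Mean total counts were lower on the sufficient diet in every node. The gene entry Rn18s-rs5 took 0.114% to 7.77% of counts in sufficient libraries. In deficient libraries it took 0.0911% to 3.6%, with at most 0.859% outside colonic replicate 2. A difference in processing was not tested and cannot be told apart from the diet. In duodenal nodes the retinoic acid-producing enzyme Aldh1a2 averaged 55 ± 16.8 CPM on the sufficient and 1.98 ± 0.73 CPM on the deficient diet (log2 fold change -4.66 ± 0.34, adjusted p = 1.3e-13). Lrat averaged 24.3 ± 4.0 and 1.28 ± 0.36 CPM (-4.29 ± 0.31, adjusted p = 5.1e-14), and Cyp26b1 5.16 ± 1.07 and 0.489 ± 0.38 CPM (-3.27 ± 0.46, adjusted p = 2.0e-06). For Aldh1a2 and for Lrat all 5 deficient libraries lay below all 5 sufficient libraries, 1 of 252 possible orders. This order leaves out sex, which differs between the diets, so it describes and does not test. Mast cell genes moved the other way. Mcpt4 averaged 0.506 ± 0.31 CPM on the sufficient and 92.5 ± 38.1 CPM on the deficient diet (7.41 ± 0.68, adjusted p = 8.8e-11), and Cma1 (7.07 ± 0.70, adjusted p = 5.9e-10) and Cpa3 (5.57 ± 0.54, adjusted p = 4.1e-10) rose with it. The tryptase Tpsb2, which shares sequence with Tpsab1 so that its counts are uncertain, averaged 0.0528 ± 0.12 and 88.5 ± 42.9 CPM (adjusted p = 5.7e-09).

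In duodenal nodes 1864 genes passed, 1138 higher and 726 lower on the deficient diet. The retinoid metabolism list (camera adjusted p = 2.7e-06, adjusted p = 0.00377 with an estimated correlation) and the retinoic acid response list (camera adjusted p = 8.2e-05, adjusted p = 0.0362 with an estimated correlation) were lower, with Hic1 (-1.41 ± 0.17, adjusted p = 5.8e-08) and Stra6 (-1.07 ± 0.32, adjusted p = 0.0245) among their members. Of 18 tested retinoid metabolism genes, 0 were higher and 7 lower over all genes, and 1 and 8 adjusted over the list alone. Among 15 tested retinoic acid response genes, 2 were higher and 8 lower over all genes, and 3 and 9 adjusted over the list alone. The mast cell list was higher (camera adjusted p = 2.7e-09, adjusted p = 0.0526 with an estimated correlation). Of 12 tested mast cell genes, 9 were higher and 0 lower over all genes, and 10 and 1 adjusted over the list alone. The gut-homing chemokine receptor Ccr9 averaged 48.3 ± 1.9 CPM on the sufficient and 25.4 ± 5.5 CPM on the deficient diet (adjusted p = 1.3e-05). The addressin Madcam1 (-0.80 ± 0.23, adjusted p = 0.0168) fell, while the colon-homing receptor Gpr15 (1.94 ± 0.18, adjusted p = 2.3e-10) and the integrin Itgae (0.87 ± 0.14, adjusted p = 3.7e-05) rose. Plasma cell genes were higher (camera adjusted p = 4.6e-05, adjusted p = 0.206 with an estimated correlation), including Mzb1 (0.96 ± 0.18, adjusted p = 3.6e-04) and the IgG genes Ighg2b (3.39 ± 0.70, adjusted p = 9.3e-04) and Ighg2c (4.44 ± 1.12, adjusted p = 0.00649), paralogs whose counts are uncertain. Among 19 tested plasma cell genes, 6 were higher and 0 lower over all genes, and 7 and 0 adjusted over the list alone. Regulatory T cell genes were higher (camera adjusted p = 6.8e-04, adjusted p = 0.151 with an estimated correlation), for example Foxp3 (0.89 ± 0.19, adjusted p = 0.00141) and Tnfrsf4 (1.08 ± 0.13, adjusted p = 1.7e-07). Of 14 tested regulatory T cell genes, 7 were higher and 2 lower over all genes, and 7 and 2 adjusted over the list alone. The dendritic cell genes Clec9a (-1.54 ± 0.18, adjusted p = 2.3e-08) and Itgax (-0.97 ± 0.12, adjusted p = 3.3e-07) fell, whereas Cd207 (2.44 ± 0.37, adjusted p = 1.1e-05) and Fscn1 (1.08 ± 0.17, adjusted p = 1.4e-05) rose. Alb, the albumin transcript of liver, averaged 51.9 ± 88.9 CPM on the sufficient and 0.759 ± 0.85 CPM on the deficient diet (adjusted p = 1.1e-04). That sufficient mean was raised by replicate 3 at 211 CPM, with the other 4 libraries between 9.26 and 15 CPM. Alb was also lower on the deficient diet in jejunal (12 ± 14.2 and 0.273 ± 0.16 CPM, -5.63 ± 1.26, adjusted p = 0.00427) and colonic nodes (11.4 ± 11 and 0.644 ± 0.34 CPM, -4.20 ± 1.05, adjusted p = 0.0196). In ileal nodes it averaged 3.77 ± 2.22 and 0.14 ± 0.15 CPM and in inguinal nodes 7.7 ± 6.97 and 1.73 ± 1.37 CPM. Apoa1 fell in duodenal (-5.81 ± 1.06, adjusted p = 1.7e-04), jejunal (-3.76 ± 1.02, adjusted p = 0.0223) and colonic nodes (-4.96 ± 1.24, adjusted p = 0.0206). The origin of these transcripts was not tested. The heat shock gene Hsph1 fell from 214 ± 104 to 65.9 ± 11.2 CPM (-1.48 ± 0.31, adjusted p = 8.8e-04), and also in jejunal (-1.15 ± 0.31, adjusted p = 0.0183), ileal (-1.07 ± 0.30, adjusted p = 0.0239) and colonic nodes (-1.08 ± 0.31, adjusted p = 0.0474). With only the libraries of 1 node it passed in none of them. The list of immediate early and heat shock genes went both ways in duodenal nodes, with 5 members higher and 3 lower. With only the 10 duodenal libraries in the fit 314 genes passed, among female mice 800, without a filter on low counts 1239 and without sufficient replicate 2, 1 of the 2 sufficient females, 1189. Without the 10 deficient libraries with low Gm19220 the count was 1553.

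**Figure D1:**
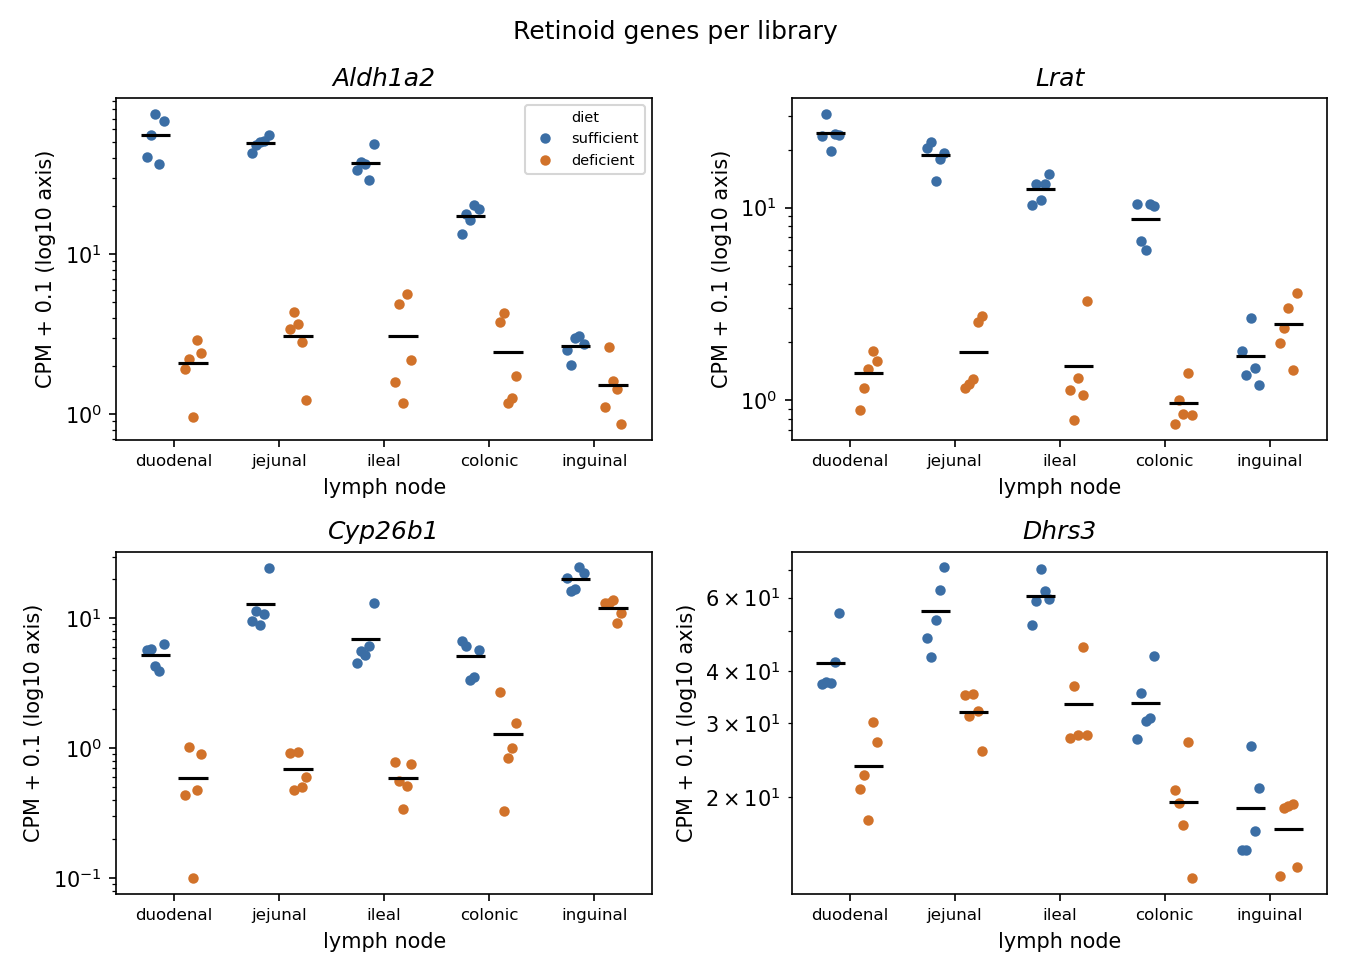
Normalised expression in CPM on a log10 axis (0.1 added to every value) of Aldh1a2, Lrat, Cyp26b1 and Dhrs3 in each of the 50 libraries, by node and diet, where points are libraries and bars are group means with n = 5. Aldh1a2 averaged 55 ± 16.8 CPM in sufficient and 1.98 ± 0.73 CPM in deficient duodenal nodes, and 2.56 ± 0.42 and 1.43 ± 0.68 CPM in inguinal nodes.

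In jejunal nodes Aldh1a2 (-3.89 ± 0.32, adjusted p = 9.9e-12), Lrat (-3.50 ± 0.29, adjusted p = 1.1e-11) and Cyp26b1 (-4.33 ± 0.43, adjusted p = 1.1e-09) fell on the deficient diet, and the retinoid metabolism list was lower (camera adjusted p = 9.5e-11, adjusted p = 2.1e-04 with an estimated correlation). Among 18 tested retinoid metabolism genes, 0 were higher and 7 lower over all genes, and 0 and 9 adjusted over the list alone. Mcpt4 rose from 0.873 ± 0.36 to 78.3 ± 18 CPM (6.39 ± 0.62, adjusted p = 6.5e-10), and the mast cell list was higher (camera adjusted p = 7.8e-15, adjusted p = 0.0108 with an estimated correlation). Of 12 tested mast cell genes, 8 were higher and 0 lower over all genes, and 9 and 0 adjusted over the list alone. Ccr9 fell (-0.82 ± 0.15, adjusted p = 4.5e-04), together with the ADP-ribosyltransferases Art2b (-2.60 ± 0.21, adjusted p = 4.2e-12) and Art2a (-2.14 ± 0.24, adjusted p = 1.9e-08), paralogs whose counts are uncertain, and the alternative macrophage marker Retnla (-2.72 ± 0.46, adjusted p = 1.1e-04). The ligand of Gpr15 (Gpr15lg) rose (3.08 ± 0.31, adjusted p = 2.2e-09), as did Gpr15 (1.51 ± 0.18, adjusted p = 1.2e-07), Itgae (1.00 ± 0.14, adjusted p = 5.1e-06) and Cd207 (2.42 ± 0.38, adjusted p = 3.4e-05). T cell genes were higher (camera adjusted p = 9.3e-05, adjusted p = 0.292 with an estimated correlation), including Il7r (0.78 ± 0.15, adjusted p = 5.9e-04). Among 16 tested T cell genes, 2 were higher and 0 lower over all genes, and 7 and 0 adjusted over the list alone. Fibroblast genes were lower (camera adjusted p = 8.9e-04, adjusted p = 0.326 with an estimated correlation). Of 15 tested fibroblast genes, 0 were higher and 3 lower over all genes, and 1 and 5 adjusted over the list alone. Pancreatic genes had a median log2 fold change of -1.42 and adipose genes one of -0.68, with no member past the threshold. Adipose genes took 0.336% ± 0.126% of counts on the sufficient and 0.193% ± 0.0611% on the deficient diet. In total 837 genes passed, 506 higher and 331 lower. Of the calls in jejunal nodes 60.5% were higher in the full fit, 52.3% among female mice and 40.4% with only the jejunal libraries. With only the jejunal libraries 178 genes passed, among female mice 264, without a filter on low counts 534 and without sufficient replicate 2 479. Without the 10 libraries with low Gm19220 the count was 678.

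In ileal nodes 1048 genes passed, 504 higher and 544 lower on the deficient diet. Aldh1a2 (-3.50 ± 0.32, adjusted p = 1.8e-10), Lrat (-3.16 ± 0.30, adjusted p = 4.7e-10) and Stra6 (-1.70 ± 0.31, adjusted p = 2.6e-04) fell, and Mcpt4 rose from 1.7 ± 1.22 to 41.2 ± 13.4 CPM (4.53 ± 0.57, adjusted p = 3.8e-07). The retinoic acid response list was lower (camera adjusted p = 9.6e-09, adjusted p = 0.00304 with an estimated correlation), and the mast cell list higher (camera adjusted p = 9.6e-09, adjusted p = 0.0626 with an estimated correlation). Among 15 tested retinoic acid response genes, 1 were higher and 7 lower over all genes, and 1 and 9 adjusted over the list alone. Of 12 tested mast cell genes, 8 were higher and 0 lower over all genes, and 8 and 0 adjusted over the list alone. T cell genes were higher (camera adjusted p = 8.6e-13, adjusted p = 0.0362 with an estimated correlation), among them Il7r (1.14 ± 0.15, adjusted p = 6.2e-07) and Tcf7 (0.74 ± 0.14, adjusted p = 4.2e-04), and the scavenger receptors Scart1 (2.92 ± 0.25, adjusted p = 2.8e-11) and Scart2 (3.00 ± 0.25, adjusted p = 7.0e-12) of gamma delta T cells, paralogs with uncertain counts, rose with them. Among 16 tested T cell genes, 8 were higher and 0 lower over all genes, and 13 and 0 adjusted over the list alone. Lymphatic endothelial genes were lower (camera adjusted p = 8.6e-09, adjusted p = 0.0489 with an estimated correlation), for example the transcription factor Prox1 (-1.23 ± 0.17, adjusted p = 1.8e-06), as were genes of follicular dendritic and marginal reticular cells (camera adjusted p = 1.1e-06, adjusted p = 0.00673 with an estimated correlation), such as Cxcl13 (-0.82 ± 0.16, adjusted p = 3.8e-04) and Tnfsf11 (-0.99 ± 0.17, adjusted p = 9.3e-05). Of 16 tested lymphatic endothelial genes, 0 were higher and 7 lower over all genes, and 0 and 9 adjusted over the list alone. Among 13 tested follicular dendritic and marginal reticular cell genes, 0 were higher and 4 lower over all genes, and 0 and 8 adjusted over the list alone. Interferon response genes were higher (camera adjusted p = 5.5e-07, adjusted p = 0.426 with an estimated correlation), including Irf7 (1.49 ± 0.41, adjusted p = 0.0199), which averaged 104 ± 32 CPM on the sufficient and 288 ± 199.6 CPM on the deficient diet. Of 18 tested interferon response genes, 6 were higher and 0 lower over all genes, and 15 and 0 adjusted over the list alone. In ileal nodes Irf7 did not pass without deficient replicate 4 (1.01, adjusted p = 0.14) or among female mice (1.10, adjusted p = 0.445). The cytotoxic genes Eomes (1.28 ± 0.18, adjusted p = 2.6e-06) and Prf1 (1.12 ± 0.15, adjusted p = 7.0e-07) and the monocyte gene Ly6c2 (1.90 ± 0.21, adjusted p = 1.3e-08) rose. With only the ileal libraries 109 genes passed, among female mice 367, and without sufficient replicate 2 658. Without the 10 libraries with low Gm19220 the count was 636.

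In colonic nodes 409 genes passed, 235 higher and 174 lower. Lrat (-3.35 ± 0.32, adjusted p = 1.4e-09), Aldh1a2 (-2.72 ± 0.34, adjusted p = 6.0e-07) and Cyp26b1 (-2.02 ± 0.40, adjusted p = 0.00229) fell, and both the retinoid metabolism list (camera adjusted p = 1.7e-07, adjusted p = 0.00217 with an estimated correlation) and the retinoic acid response list (camera adjusted p = 1.2e-07, adjusted p = 0.00439 with an estimated correlation) were lower. Among 18 tested retinoid metabolism genes, 0 were higher and 6 lower over all genes, and 2 and 8 adjusted over the list alone. Of 15 tested retinoic acid response genes, 1 were higher and 5 lower over all genes, and 1 and 9 adjusted over the list alone. Mcpt4 averaged 0.906 ± 0.63 CPM on the sufficient and 5.19 ± 6.93 CPM on the deficient diet (adjusted p = 0.0604). The macrophage gene Retnla (-3.71 ± 0.50, adjusted p = 2.7e-06) and the chemokines Ccl17 (-1.80 ± 0.36, adjusted p = 0.00222) and Ccl22 (-0.81 ± 0.16, adjusted p = 0.00222) fell, while the plasma cell list was higher (camera adjusted p = 1.1e-10, adjusted p = 0.0298 with an estimated correlation), with Mzb1 (0.89 ± 0.18, adjusted p = 0.00279) and Prdm1 (1.07 ± 0.26, adjusted p = 0.0144). Among 19 tested plasma cell genes, 7 were higher and 0 lower over all genes, and 12 and 1 adjusted over the list alone. Interferon response genes were higher (camera adjusted p = 1.1e-11, adjusted p = 0.244 with an estimated correlation), for example Oas3 (2.00 ± 0.50, adjusted p = 0.0209) and Irf7 (1.70 ± 0.42, adjusted p = 0.0179). Of 18 tested interferon response genes, 7 were higher and 0 lower over all genes, and 18 and 0 adjusted over the list alone. The deficient libraries differed widely, with Irf7 at 63.8 ± 13.7 CPM on the sufficient and 205 ± 132 CPM on the deficient diet. It did not pass without deficient replicate 2 (1.29, adjusted p = 0.146) or among female mice (1.46, adjusted p = 0.433). Cd207 (3.02 ± 0.41, adjusted p = 3.5e-06), Ly6c2 (1.76 ± 0.21, adjusted p = 1.8e-07) and Eomes (1.04 ± 0.18, adjusted p = 2.7e-04) rose as well. Adipose genes had a median log2 fold change of -0.60 with no member past the threshold. They took 0.264% ± 0.113% of counts on the sufficient and 0.142% ± 0.061% on the deficient diet. The balance of directions was not stable. Of the calls in colonic nodes 57.5% were higher in the full fit, 28.7% among female mice and 31.8% with only the colonic libraries. With only the colonic libraries 44 genes passed, among female mice 122, and without sufficient replicate 2 or deficient replicate 2 the count was 229 and 253. Without the 10 libraries with low Gm19220 it was 132.

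In inguinal nodes 154 genes passed, 99 higher and 55 lower. Art2b (-2.48 ± 0.22, adjusted p = 1.8e-10), the lymphocyte GTPase Gimap7 (-1.18 ± 0.10, adjusted p = 1.8e-10) and Ccr9 (-0.68 ± 0.15, adjusted p = 0.015) fell. The transcription factor Zbtb16 (2.17 ± 0.32, adjusted p = 6.7e-05), the retinal dehydrogenase Aldh1a1 (1.69 ± 0.40, adjusted p = 0.0232), Gpr15 (1.19 ± 0.19, adjusted p = 2.0e-04) and Cd207 (1.65 ± 0.33, adjusted p = 0.00547) rose, and so did Cpa3 (2.21 ± 0.47, adjusted p = 0.0101) and Mcpt4 (2.27 ± 0.53, adjusted p = 0.0226). Aldh1a2 (-0.70 ± 0.41, adjusted p = 0.529) and Cyp26b1 (-0.67 ± 0.33, adjusted p = 0.427) did not pass. Cyp26b1 nevertheless lay at 9.18 to 13.7 CPM in the deficient and at 16.1 to 24.7 CPM in the sufficient libraries, without overlap, whereas Aldh1a2 overlapped. T cell genes were lower (camera adjusted p = 1.6e-08, adjusted p = 0.0975 with an estimated correlation), including the transcription factor Lef1 (-0.79 ± 0.13, adjusted p = 2.0e-04) and Cd28 (-0.52 ± 0.10, adjusted p = 0.00261). Among 16 tested T cell genes, 0 were higher and 3 lower over all genes, and 0 and 5 adjusted over the list alone. Adipose genes were higher (camera adjusted p = 2.3e-06, adjusted p = 0.406 with an estimated correlation). Of 17 tested adipose genes, 1 were higher and 0 lower over all genes, and 5 and 0 adjusted over the list alone. Ucp1 of brown fat averaged 2.55 ± 4.71 and 8.56 ± 9.93 CPM (adjusted p = 0.032). The balance of directions turned in smaller fits. Of the calls in inguinal nodes 64.3% were higher in the full fit, 44% among female mice and 41.2% with only the inguinal libraries. With only the inguinal libraries 17 genes passed, among female mice 50, without a filter on low counts 96, with DESeq2 268, and without the 10 libraries with low Gm19220 35. Without sufficient replicate 1 or 2, or deficient replicate 2 or 3, the count was 53, 73, 82 and 95.

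**Figure D2:**
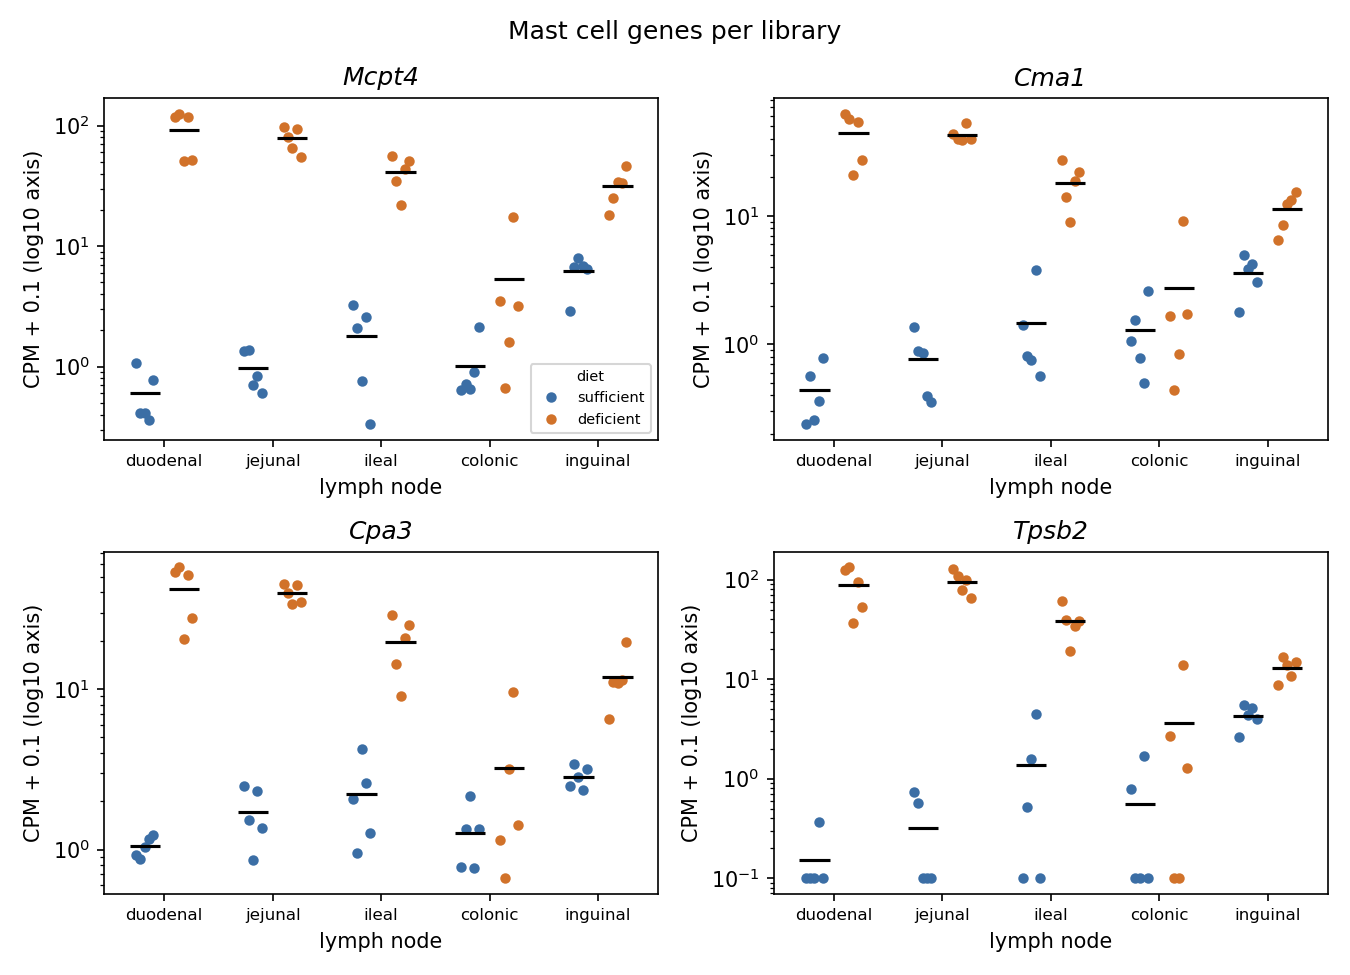
Normalised expression in CPM on a log10 axis (0.1 added to every value) of the mast cell genes Mcpt4, Cma1, Cpa3 and Tpsb2 in each of the 50 libraries, by node and diet, where points are libraries and bars are group means with n = 5. Mcpt4 averaged 0.506 ± 0.31 CPM in sufficient and 92.5 ± 38.1 CPM in deficient duodenal nodes, and 0.906 ± 0.63 and 5.19 ± 6.93 CPM in colonic nodes.

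Across the 5 nodes 32 genes were higher and 17 lower on the deficient diet in every node. The genes lower in every node included Ccr9, Art2b, Gimap3, Gimap4, Gimap6, Gimap7, Asb2 and Izumo1r, the folate receptor of regulatory T cells. Those higher in every node included Gpr15, Itgae, Cd207, S100a4, Zbtb16 and the glucocorticoid-induced chaperone Fkbp5. These genes were listed by the number of nodes, after their values were seen. The nodes hold different libraries, but all 5 tests share the estimate of the sex effect, which rests on the sufficient mice, so the overlap was not tested. Among 2765 genes past the threshold in at least 1 node, 3 went in opposite directions in different nodes.

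Whether the diet acted differently by region was tested directly with interaction terms. Between gut-draining and inguinal nodes 169 genes passed, 73 with a higher and 96 with a lower diet effect in gut-draining nodes. Lrat had the clearest such difference (-4.12 ± 0.34, adjusted p = 4.5e-11), and the diet also lowered Aldh1a2 (-2.99 ± 0.45, adjusted p = 8.5e-05) and Cyp26b1 (-2.65 ± 0.38, adjusted p = 3.1e-05) more in gut-draining nodes. Mcpt4 (2.91 ± 0.55, adjusted p = 0.0022), Cma1 (2.80 ± 0.56, adjusted p = 0.00554) and Gpr15lg (2.11 ± 0.29, adjusted p = 2.5e-05) went the other way. In sufficient inguinal nodes Lrat (1.09 to 2.57 CPM) and Aldh1a2 (1.94 to 3.00 CPM) were already low, which left little room to fall. Cyp26b1 lay at 16.1 to 24.7 CPM there. Interaction values of the retinoid metabolism list were lower (camera adjusted p = 2.3e-10, adjusted p = 2.1e-04 with an estimated correlation), those of T cell genes higher (camera adjusted p = 8.2e-22, adjusted p = 0.00396 with an estimated correlation), for example Cd28 (0.56 ± 0.11, adjusted p = 0.0022) and Tcf7 (0.66 ± 0.15, adjusted p = 0.0138), and those of follicular dendritic and marginal reticular cells lower (camera adjusted p = 1.2e-06, adjusted p = 0.00673 with an estimated correlation). Among 18 tested retinoid metabolism genes, 0 were higher and 5 lower over all genes, and 0 and 7 adjusted over the list alone. Of 16 tested T cell genes, 9 were higher and 0 lower over all genes, and 14 and 0 adjusted over the list alone. Among 13 tested follicular dendritic and marginal reticular cell genes, 0 were higher and 1 lower over all genes, and 0 and 5 adjusted over the list alone. Adipose genes had a median of -1.62 with no member past the threshold over all genes. Among female mice 29 genes passed, without the 10 libraries with low Gm19220 19, without a filter on low counts 111 and with DESeq2 298. With the replicate number as a fixed block 273 genes passed, 49.5% of them with a higher diet effect. The share with a higher diet effect was 43.2% in the full fit, 55.2% among female mice, 57.9% without the low-Gm19220 libraries and 51% with DESeq2. Leaving out 1 number at a time gave 78 (without sufficient replicate 2) to 217 genes. The count was 85, 78, 95 and 112 without sufficient replicates 1, 2, 4 and 5 in turn. It was 87, 86 and 98 without deficient replicates 2, 3 and 4.

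Between small intestinal and colonic nodes 15 genes passed, each with a higher diet effect in small intestinal nodes. That uniform direction was not stable, since without the 10 libraries with low Gm19220 5 genes passed, 2 of them among the 15, and 40% were higher. With DESeq2 79.5% of the calls were higher. The 15 included Cma1 (4.42 ± 0.79, adjusted p = 0.0029) and Cpa3 (3.03 ± 0.65, adjusted p = 0.0398) of mast cells, Il1rl1 (2.33 ± 0.41, adjusted p = 0.0029), which is outside the mast cell list, Gpr15lg (1.93 ± 0.31, adjusted p = 7.9e-04), the calcium-binding protein S100a4 (1.03 ± 0.15, adjusted p = 2.4e-04) and the protease Asprv1 (1.75 ± 0.28, adjusted p = 6.8e-04). The mast cell list was higher as a group (camera adjusted p = 3.6e-14, adjusted p = 0.0124 with an estimated correlation). Of 12 tested mast cell genes, 2 were higher and 0 lower over all genes, and 5 and 0 adjusted over the list alone. Aldh1a2 did not pass (-1.29 ± 0.38, adjusted p = 0.335). Between duodenal and ileal nodes 41 genes passed, 34 with a higher and 7 with a lower diet effect in duodenal nodes. The dendritic cell chemokine Ccl22 (1.39 ± 0.21, adjusted p = 6.4e-04), the collagen Col12a1 (1.31 ± 0.20, adjusted p = 7.8e-04) and Fscn1 (0.95 ± 0.22, adjusted p = 0.0417) were higher, and the integrin Itgax (-0.73 ± 0.16, adjusted p = 0.0382) and the vascular factor Angpt2 (-1.57 ± 0.35, adjusted p = 0.0344) lower. T cell genes had lower interaction values (camera adjusted p = 1.1e-11, adjusted p = 0.0426 with an estimated correlation). Among 16 tested T cell genes, 0 were higher and 0 lower over all genes, and 0 and 8 adjusted over the list alone. In the first of these tests DESeq2 called 39 genes, limma-voom 8, edgeR among female mice 1, edgeR without the low-Gm19220 libraries 5, and edgeR without sufficient replicate 5, deficient replicate 1 or deficient replicate 2 7, 8 and 8. The duodenal against ileal count was 13, 4 and 2 without sufficient replicates 1, 3 and 4 in turn. It was 14, 5, 17 and 26 without deficient replicates 1, 2, 4 and 5. This count was 9 without a filter on low counts, 13 without a sex term, 19 without the low-Gm19220 libraries and 128 with DESeq2. With the replicate number as a block 97 genes passed (fixed factor) and 84 (random effect). Without the 2 libraries with a high pancreatic share 26 passed. Among female mice edgeR called 0 genes, with 1076 at an unadjusted p under 0.05.

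For the main genes of these comparisons, positions in GRCm38 (GENCODE M21), found by the Ensembl gene identifier of the count table, were as follows. Aldh1a2 (ENSMUSG00000013584) lies on chromosome 9 at 71215789 to 71296243. Lrat (ENSMUSG00000028003) lies on chromosome 3 at 82892579 to 82903973, and Cyp26b1 (ENSMUSG00000063415) on chromosome 6 at 84571414 to 84593908. Mcpt4 (ENSMUSG00000061068) lies on chromosome 14 at 56059629 to 56062313, and Nkx2-3 (ENSMUSG00000044220) on chromosome 19 at 43612325 to 43615892. All 5 are annotated there as protein-coding genes, while Gm19220 (ENSMUSG00000113337), on chromosome 12 at 40893485 to 40894287, is annotated as a processed pseudogene. Counts are per gene, so they do not separate exons or transcripts.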

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

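The tests of explanations in this part, their bounds and the number of splits were chosen after the results were seen. The bound on the share of duodenal against ileal calls kept without 2 libraries was raised once its values were known, which left the deficient diet open. Other assignments of the libraries to the groups were drawn, 60 per comparison with the real one among them, a number raised from 40 after the first draws. In every comparison the real assignment alone (1 of 60) gave as many genes. A chance division of the libraries is not excluded by this, since only 60 assignments were drawn. Wrong assignments also leave any true difference in the spread within groups, which lowers their counts. The diet effect called 1864, 837, 1048, 409 and 154 genes from duodenal to inguinal nodes, and the highest other assignment 303, 27, 77, 11 and 11. On the sufficient diet the 3 regional contrasts called 3108, 705 and 1484 genes, against at most 63, 198 and 57. On the deficient diet they called 1050, 325 and 1029, against at most 401, 92 and 24.

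The diet effect differed between regions in tests of the interaction. Between gut-draining and inguinal nodes 169 genes differed (highest other assignment 10), with log2 values of -4.12 for Lrat, -2.99 for Aldh1a2, -2.65 for Cyp26b1, 2.91 for Mcpt4, 2.80 for Cma1, 2.11 for Gpr15lg, 0.56 for Cd28 and 0.66 for Tcf7. Between small intestinal and colonic nodes 15 genes differed (highest other assignment 0), with 4.42 for Cma1, 3.03 for Cpa3, 2.33 for Il1rl1, 1.93 for Gpr15lg, 1.03 for S100a4 and 1.75 for Asprv1. Between duodenal and ileal nodes 41 genes differed (highest other assignment 2), with 1.39 for Ccl22, 1.31 for Col12a1, 0.95 for Fscn1, -0.73 for Itgax and -1.57 for Angpt2.

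Mast cell genes were higher on the deficient diet in small intestinal nodes, with list medians of 4.76, 3.97 and 3.32 on the log2 scale in duodenal, jejunal and ileal nodes. With an estimated correlation camera called the list in jejunal nodes (adjusted p = 0.0108) but not in duodenal (0.0526) or ileal nodes (0.0626). Among female mice the lowest of the 3 medians was 2.63, which argues against sex as the whole source, although only 2 sufficient females per node stand behind it. Without the 10 libraries with low Gm19220 the lowest was 3.05, which argues against that class of libraries. A difference in litter, in the handling of the tissue or in tissue taken with the node was not tested and stays open beside the diet.

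Gm19220 was low in 10 of the 25 deficient libraries and high in the other 15, which argues against the diet as the whole source. Without overlap 5 genes (Grip2, C2cd4c, Gm15039, Gm26822 and Gm19220 itself) separated the 10 from the 15, where the highest of 100 random draws gave 3. The 10 were ileal, colonic and inguinal replicate 2, every node of replicate 3, and colonic and inguinal replicate 5 of the deficient diet. In the order of the samples they form unbroken runs, as a batch in processing could give. The labels name no batch. Gm19220 defined the class, so it is 1 of the 5.

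Pancreatic genes took 27.5% of counts in sufficient duodenal replicate 5 and 25.2% in deficient duodenal replicate 4, each far from the other 4 libraries of its group. Over the 10 duodenal libraries the shares of the members within the list had a median SD of 0.275 on the log2 scale, against an SD of 3.77 for the total, as RNA from pancreatic tissue next to the node could give. Of the duodenal against ileal calls outside the list, 82.4% on the sufficient diet were called without these 2 libraries, which argues against scaling by a few genes as the main source there. On the deficient diet 69.6% were, and whether the rest was lost to scaling or to fewer libraries cannot be told apart.

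Single libraries lay far from the other 4 of their group in 13 of 75 sets of values with more than 1 library above 0. The limit used is passed in about 1 in 20 sets by chance only where values are normally distributed. Every set past it stood out at its high end, as skewed values could give, so that rate is no baseline here. The sets are also not independent, since 4 of those past the limit hold the pancreatic share of sufficient replicate 5. The pancreatic share was 0.453% in sufficient ileal replicate 5, 0.411% in sufficient colonic replicate 5 and 0.0364% in sufficient inguinal replicate 5. It was 0.0144% in deficient ileal replicate 4 and 0.00864% in deficient colonic replicate 1. Nkx2-3 was at 0.151 CPM in sufficient inguinal replicate 3 and at 0 in the other 4, so it stands apart by construction. Tpsb2 was at 0.264 CPM in sufficient duodenal replicate 4 and at 0 in the other 4, for the same reason. Alb reached 211 CPM in sufficient duodenal replicate 3 and at most 15 CPM in the others. It reached 36.7 CPM in sufficient jejunal replicate 5 and at most 11.2 CPM in the others. Rsad2 reached 125 CPM in deficient ileal replicate 4 and at most 28 CPM in the others. Mcpt4 reached 2.02 CPM in sufficient colonic replicate 5 and 17.4 CPM in deficient colonic replicate 4, and Ucp1 10.9 CPM in sufficient inguinal replicate 3.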

How the results depend on the processing

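Leaving out the 10 libraries with low Gm19220, a term for that class and leaving out the 2 libraries with a high pancreatic share were chosen after the data were seen. Of 201 gene values named in the text, 171 kept their side of the threshold whichever number was left out and 124 under every alternative, and none reversed. Among female mice the regional contrasts of the sufficient diet called 1136, 79 and 136 genes (gut-draining against inguinal, small intestinal against colonic, duodenal against ileal), the diet effect 800, 264, 367, 122 and 50 from duodenal to inguinal nodes, and the interactions 29, 1 and 0. That 0 of edgeR stood beside 1076 genes at an unadjusted p under 0.05. With only the libraries of a node the diet effect called 314, 178, 109, 44 and 17 genes. Fewer samples entered both settings. Without the low-Gm19220 libraries the deficient contrasts called 447 (gut-draining against inguinal) and 84 (small intestinal against colonic), the diet effect 636, 132 and 35 in ileal, colonic and inguinal nodes, and the interactions 19, 5 and 19. These libraries were spread unevenly, 1, 1, 2, 3 and 3 from duodenal to inguinal nodes. A term for the class itself called 9 genes. With it the same contrasts called 939 and 234 genes, the diet effect in the same nodes 945, 331 and 124, and the interactions 172, 10 and 33. Without the 2 high-pancreas libraries the duodenal against ileal interaction called 26.

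Without a filter on low counts the diet effect called 1239, 534 and 96 in duodenal, jejunal and inguinal nodes and the gut-draining and duodenal interactions 111 and 9. DESeq2 called 268 for the diet in inguinal nodes and 298, 39 and 128 for the interactions, limma-voom 8 for small intestinal against colonic, and a fit with no sex term 13 for duodenal against ileal. For these shifts the cause was not tested. With no sex term the diet effect called 1582, 889, 1343, 589 and 106 genes from duodenal to inguinal nodes. Of the calls in the full fit it kept 1177 of 1864, 560 of 837, 826 of 1048, 302 of 409 and 66 of 154. Many diet calls thus depend on the sex term. Leaving out 1 number of a diet gave 2197 to 2871, 395 to 609 and 833 to 1389 genes in the 3 sufficient contrasts, 733 to 959, 172 to 341 and 474 to 1142 in the deficient ones, 1189 to 2017, 479 to 895, 658 to 1221, 229 to 483 and 53 to 220 for the diet, and 78 to 217, 7 to 19 and 2 to 39 for the interactions. Camera called 184 of 518 list tests with the preset correlation, 48 with an estimated one, and fry 152. Over genes past the threshold in either diet, the correlation of regional fold changes was 0.715, 0.472 and 0.867, genes chosen for their size. Among female mice the gut-draining against inguinal value was 0.611 over such genes and 0.356 over all genes, where all libraries gave 0.551.

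The replicate numbers did not pair the nodes by the set rule, since 59 of 100 same-number pairs correlated above 0.1 (lowest -0.198) and 38 of 50 libraries correlated best with their own number. Of other-number pairs 51 of 400 lay above 0.1, and the median was 0.133 within and -0.0358 between numbers. Xist lay at 38.9 to 57.1 CPM in all 5 libraries of sufficient replicate 3 and at most 19.5 CPM in the other 10 male libraries. Sex was also the same in every node of a number. These values argue that a number marks a mouse, although the labels do not state it and some same-number pairs correlated below 0. In that case the nodes of a number would not be independent, whereas the main fit treats them as separate. Its p-values, and the sex term that enters every diet test, would then rest on fewer mice than libraries. With a replicate block as a fixed factor the gut-draining and duodenal interactions called 273 and 97 genes, and with a replicate block as a random effect the duodenal interaction 84. That random effect, fitted with limma-voom, gave diet counts of 1565, 701, 913, 280 and 107 from duodenal to inguinal nodes. Limma-voom without a block gave 1775, 806, 1034, 336 and 141, so part of the drop from the full fit came with the method. A block across diets raised them, to 2079, 981, 1184, 620 and 189.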

Other observations

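In the same fit the sex term, which compares male with female sufficient mice, called 4830 genes, 2509 higher and 2321 lower in males. Glycam1 was lower in males (log2 fold change -2.08 ± 0.15, edgeR adjusted p = 9.5e-14). The term was read after the data were seen, rests on 2 female and 3 male numbers, and treats the 5 nodes of a number as separate.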
